A study of Rattus norvegicus with 20 samples.

How the data were processed

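Expression was measured in liver RNA of 20 rats, 1 array each, in 4 diet groups of 5: control, BNF, D3T and OLT. Per the labels, biotin-labelled RNA was hybridized to 1-colour Affymetrix arrays, and the authors made the values with GCRMA, which corrects background, normalizes between arrays and summarizes probes; its version is not stated. The deposited values are probe set summaries on the log2 scale, between 0.083 and 16.46, and were used as given. Any array control probe sets were left out, and 31042 probe sets remained, to which the range above refers. The table holds no scan dates or detection calls, so scan batches could not be looked for. The largest shift of a group's median of kept probe sets against control was 0.047.

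Probe sets were named through the platform annotation supplied with the series, updated by gene identifier where the RefSeq gene table allowed. Of all probe sets 20826 had 1 gene, 436 several and 9780 none; of those with 1 gene, 20758 were updated and 68 kept their old name. Only probe sets with 1 gene name a gene here. Positions are not given. Coordinates in the RefSeq gene table were used to order genes in 1 test of the closing section. Probe sets with a log2 value above 4 in at least 5 arrays were kept, 12947 in all, of which 10047 had 1 gene, 295 several and 2605 none. For gene-level results each of the 7837 genes was represented by its kept probe set with the highest mean over all arrays; 1699 genes had more than 1 kept probe set. Group means under about 4 lie at the background level that GCRMA leaves, and differences that start or end there depend on it. Gsta2 and Cyp2b1, chosen as anchors, had no kept probe set of their own.

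Tests were made in R 4.3.3 with limma 3.58.1, by lmFit and eBayes with an intensity trend on 1 fit of all 20 arrays with a mean per diet, two-sided, at a Benjamini-Hochberg adjusted p under 0.05 over kept probe sets, for 6 comparisons: each diet with control, and the diets with each other. A gene takes the adjusted p of the probe set that represents it, except where the mean of a gene's probe sets was tested. A second count required a 2-fold difference as well. Standard errors (SE) and 95% intervals come from the moderated variances, and every p printed for a single gene is adjusted. The replicate number was not used as a block, since nothing states that rats of one number belong together.

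Of 34 gene lists fixed beforehand, 31 had at least 5 measured genes and were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison; lists of neutrophil, erythrocyte and pancreas markers had 2, 4 and 4 measured genes and were not tested. Beside each list stand the members called at the p adjusted over all kept probe sets, written below as over all genes. Members called when adjusted over the list alone are given as well. Camera was repeated with the correlation estimated per list, and the lists were also tested with fry, which asks whether a list's genes move one way on balance. In every list called in a comparison with control or between OLT and D3T, the median, the mean and the direction of the test had the same sign. Lists share genes: 22 of 33 measured Nrf2 targets, 4 of 11 AhR targets and 4 of 9 genes of NADPH supply were also in another list. Calls of such lists are therefore not separate results.

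Genes to name were set by rule: anchors, among them Cyp1a1, Cyp1a2, Nqo1, Gclc, Gsta2, Akr7a3, Cyp2b1 and Cyp7a1; in each comparison with control and in OLT versus D3T, the 5 largest increases and 5 largest decreases among called genes whose groups did not overlap; up to 3 called members per called list, and 2 for other lists described; and in the remaining comparisons the 3 largest increases and decreases. OLT versus D3T had no called gene, so the genes named there were taken from the comparisons with control, a choice made after this had been seen. Correlations of changes were set beside 100 simulations of unchanged groups with shared controls and beside all splits of the controls.

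The choices above, apart from that one, were made before the data were examined. Alternatives fixed then were centring on the median, a further quantile normalization, no filter, a stricter filter (log2 above 6), eBayes without the trend or with a robust prior, array weights, a fit of only the groups compared, the replicate number as a block, the mean of a gene's probe sets, and leaving out each array in turn. Leaving out the arrays labelled D3T 5 and OLT 1, and using each array's interquartile range as a covariate, were added after the data had been seen. The methods were tested on 20 simulated arrays in 4 groups of 5, with 200 changed probe sets among the 12947 in the D3T group. Of these, 79 of 100 changed 2-fold and 96 of 100 changed 4-fold were recovered, and 5 of 180 calls (2.78%) were of unchanged probe sets. The noise was drawn independently for each probe set. In the real arrays 29.4% of the residual variance lay on the first component, so these shares need not hold there.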

Results

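Liver RNA was measured on Affymetrix 1-colour expression arrays in 20 female Sprague Dawley rats, 1 array per rat, after 24 days on one of 4 diets. Each diet was given to 5 rats. The control rats ate the unsupplemented diet. The BNF rats received 5,6-benzoflavone, a ligand of the aryl hydrocarbon receptor (AhR), at 1650 mg per kg of diet. The other two groups received dithiolethiones, compounds known to activate the transcription factor Nrf2: D3T, the unsubstituted dithiole-thione ring, at 600 mg per kg of diet, and OLT (oltipraz), the same ring with a methyl and a pyrazinyl group, at 500 mg per kg of diet. Of the 31042 probe sets, 12947 had a log2 value above 4 in at least 5 arrays and were tested; they name 7837 genes. The number of arrays limits the precision of every value below.

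Arrays resembled each other closely, with correlations across kept probe sets between 0.930 and 0.992, but 2 arrays had a higher mean correlation with the other dithiolethione group than with their own. The closest array lay in the other dithiolethione group for these 2 and for the array labelled D3T 1 (closest to OLT 5, r = 0.977). The same held for OLT 2 and OLT 4, each closest to D3T 5 (r = 0.989 and 0.986). The array labelled D3T 5 was most similar to the array labelled OLT 2, with r = 0.989 across probe sets; its mean r was 0.968 with the other D3T arrays and 0.979 with the OLT arrays. The array labelled OLT 1 was most similar to the array labelled D3T 2 (r = 0.979), with a mean r of 0.963 with the other OLT arrays and 0.966 with the D3T arrays. On a scale running from 0 at the mean of the other OLT arrays to 1 at the mean of the other D3T arrays, the array labelled D3T 5 had a median position of 0.158 over 226 probe sets, and the array labelled OLT 1 a position of 0.807. Each remaining array, placed by the arrays other than itself and these 2, stood between 0.854 and 0.987 (D3T) or between 0.0378 and 0.221 (OLT). Akr1b8, an aldo-keto reductase, read 5.77 in the array labelled D3T 5 and 13.61 in the array labelled OLT 1. Total counts are therefore also given without these 2 arrays, and so are some values of single genes and lists, a choice made after the data had been seen. This holds for BNF versus control as well, since the 2 arrays enter the variance estimate shared by all comparisons.

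**Figure D1:**
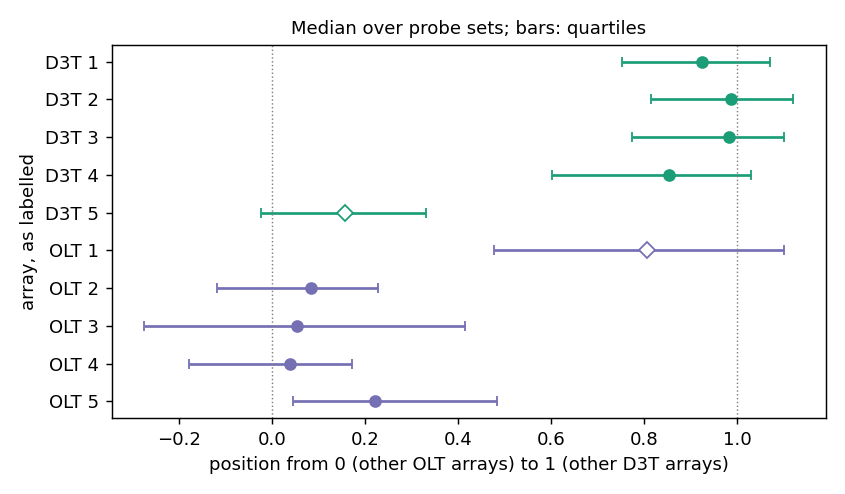
Position of each dithiolethione array (vertical axis, as labelled) on a scale without unit from 0, the mean of the other OLT arrays, to 1, the mean of the other D3T arrays; points are medians over probe sets, bars run between the quartiles, and open diamonds mark the arrays labelled D3T 5 and OLT 1. The array labelled D3T 5 lies at 0.158 and the array labelled OLT 1 at 0.807, each on the side of the other group.

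BNF versus control addresses the response of the liver to an AhR ligand. The largest increases among called genes were of 2 cytochrome P450 genes that AhR is known to drive. Cyp1a1 (gene ID 24296), a cytochrome P450, rose from 5.26 ± 1.07 to 13.59 ± 0.12 on the log2 scale (mean ± SD, n = 5 each), a difference of 8.33 (SE 1.01, adjusted p = 6.40e-05). Cyp1b1, of the same family, rose by 10.58 (SE 0.11, adjusted p = 6.53e-23), from a control mean of 2.48 that lies at background, so that the size of this change rests on the background level. Cyp1a2, already abundant in control liver at 13.88 ± 0.21, rose by 0.99 (SE 0.18, adjusted p = 0.00406). The quinone reductase Nqo1 rose by 3.22 (SE 0.38) and the aldehyde dehydrogenase Aldh3a1 by 5.26 (SE 0.29), the latter from a control mean of 2.98 at background. Of 11 measured AhR targets, 6 rose and none fell over all genes, with a median of 0.99; adjusted over the list alone, 7 rose. Limma's camera gave the list an adjusted p of 5.25e-19, and adjusted p = 3.95e-05 with an estimated correlation. Outside this list, the largest increases were of Rbm24, an RNA-binding protein, by 7.42 (SE 0.14), and of Lcn2, the iron-siderophore binding lipocalin 2, by 5.77 (SE 0.37), each from a control mean under 2.5 at background.

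Some genes of amino acid breakdown and of fatty acid oxidation fell under BNF; neither list was called with an estimated correlation. Of 31 measured genes of amino acid catabolism and the urea cycle, 9 fell and none rose; adjusted over the list alone, 11 fell. The list had a median of -0.26 and an adjusted p of 1.32e-06 (adjusted p = 0.0752 with an estimated correlation). Its members Gpt, alanine aminotransferase, fell by 1.88 (SE 0.26), Prodh, proline dehydrogenase, by 1.25 (SE 0.16), and Gls2, liver glutaminase, by 1.25 (SE 0.16). Of 28 measured genes of fatty acid oxidation and PPARa targets, 8 fell, or 14 adjusted over the list alone, with a median of -0.47 (adjusted p = 1.02e-08; adjusted p = 0.149 with an estimated correlation). Cpt2, the inner carnitine palmitoyltransferase, fell by 0.80 (SE 0.15), and Acadm, medium-chain acyl-CoA dehydrogenase, by 0.59 (SE 0.11). Among 20 measured genes of cholesterol synthesis and uptake, 2 fell, or 7 adjusted over the list alone, with a median of -0.57 (adjusted p = 1.02e-04; adjusted p = 0.376 with an estimated correlation). Neither of the 2, Stard4 and Hsd17b7, was called without the array labelled control 1, control 2, control 5, BNF 1 or BNF 5 (adjusted p from 0.0535 to 0.141). Members of the list not called as labelled were not followed there. Stard4 was also lost without BNF 2 (adjusted p = 0.108), and Hsd17b7 without control 4 or BNF 3 (adjusted p = 0.0643 and 0.0762). Neither was called after centring, without a filter or with only the 2 groups. Among single genes with the largest decreases, the Kazal-type peptidase inhibitor Spink1l fell by 5.09 (SE 0.62), the asparaginase Aspg fell by 4.36 (SE 0.34), and the activin subunit gene Inhba fell by 3.48 (SE 0.76), to a mean of 2.51 at background. The D-amino acid oxidase Dao fell by 2.77 (SE 0.57).

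Some markers of cells other than hepatocytes were higher under BNF than in control; of the 5 lists, camera called all at the preset correlation and none with an estimated one. Of 14 measured stellate cell and fibroblast markers, 6 rose and none fell, 8 adjusted over the list alone, with a median of 0.76 (adjusted p = 1.37e-09; adjusted p = 0.0752 with an estimated correlation). The collagen genes Col1a1 and Col3a1 rose by 2.45 (SE 0.38) and 0.95 (SE 0.19). For 17 macrophage and Kupffer cell markers the median was 0.93, with 2 rising over all genes and 11 adjusted over the list alone (adjusted p = 1.59e-11; adjusted p = 0.149 with an estimated correlation); Tyrobp, a signalling adaptor of myeloid cells, rose by 0.93 (SE 0.20). The other of the 2, Laptm5, was not called when any one of control 1, control 2, control 4, control 5, BNF 1, BNF 2, BNF 4 or BNF 5 was left out (adjusted p from 0.0590 to 0.116). Of 7 lymphocyte and NK cell markers, 2 rose, or 4 adjusted over the list alone. Of the 2, Cd74 was not called without the array labelled control 2 (adjusted p = 0.0510). The list had a median of 0.60 (adjusted p = 1.11e-04 by camera, or 0.0752 with an estimated correlation). No endothelial marker of 12 was called by limma, over all genes or over the list alone, while the list had a median of 0.67 (adjusted p = 2.84e-04; adjusted p = 0.314 with an estimated correlation and 0.132 by fry). Of 7 cholangiocyte markers 1 rose, or 2 adjusted over the list alone, with a median of 0.28 (adjusted p = 0.0156; adjusted p = 0.0752 with an estimated correlation and 0.0809 with the stricter filter). That 1, Aqp1, was not called when any one of control 2, control 3, control 4, control 5, BNF 1, BNF 2, BNF 4 or BNF 5 was left out (adjusted p from 0.0755 to 0.124), nor after centring, without a filter or with only the 2 groups.

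Of 24 measured acute phase and complement genes, 3 rose under BNF, or 6 with 1 falling adjusted over the list alone (median 0.12, adjusted p = 5.89e-07; adjusted p = 0.314 with an estimated correlation). They were Lcn2, the interleukin 1 receptor gene Il1r1, which rose by 2.01 (SE 0.43), and Orm1, an acid glycoprotein, which rose by 0.86 (SE 0.19). Of 33 Nrf2 targets, 2 rose, or 5 adjusted over the list alone (median 0.20, adjusted p = 8.84e-05; adjusted p = 0.430 with an estimated correlation and 0.258 by fry). Beside Nqo1 the other was Nfe2l2, not called without control 4, control 5, BNF 1, BNF 2 or BNF 4 (adjusted p from 0.0520 to 0.0896). Nqo1 and Nfe2l2 are also in the list of AhR targets, so that these 2 calls are not separate from that list. Of 18 glutathione S-transferases none was called over all genes as labelled, and 8 rose and 3 fell adjusted over the list alone. The median was 0.14 (adjusted p = 0.00849 by camera, 0.519 with an estimated correlation and 0.334 by fry). Without the arrays labelled D3T 5 and OLT 1, which enter the shared variance estimate, 5 glutathione S-transferases and 7 Nrf2 targets were called higher over all genes, and none lower. With an estimated correlation camera called neither list there (adjusted p = 0.1855 for both). Akr7a3 and Cyp7a1, anchors of the comparison, gave -0.01 (95% interval -1.29 to 1.27) and -0.04 (-1.15 to 1.08), and Gclc, the catalytic subunit of glutathione synthesis, gave -0.20 (-0.58 to 0.19). These differences stayed the same without the arrays labelled D3T 5 and OLT 1. Their SE went from 0.61 to 0.28 for Akr7a3, from 0.53 to 0.51 for Cyp7a1 and from 0.18 to 0.12 for Gclc.

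In total limma called 450 probe sets between BNF and control, 189 higher and 261 lower, for 327 genes; 177 also differed at least 2-fold, 103 higher and 74 lower. The split between higher and lower moved with the scaling: after quantile normalization 311 were higher and 261 lower. The count was 297 without the array labelled control 2, 263 without BNF 1 and 291 without BNF 2.

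D3T versus control addresses the response to the parent dithiolethione. Many Nrf2 targets, glutathione S-transferases and genes of NADPH supply rose, and many heat shock genes, genes of fatty acid oxidation and some pericentral markers fell; with an estimated correlation camera called 0 lists as labelled (6 at an unadjusted p under 0.05). Akr7a3 (gene ID 26760), a reductase of aflatoxin aldehydes, rose from 9.14 ± 0.41 to 13.50 ± 1.22 (n = 5 each), by 4.36 (SE 0.61, adjusted p = 1.61e-04), or by 4.89 without the arrays labelled D3T 5 and OLT 1. Akr1b8 rose by 8.06 (SE 1.54) from a control mean of 4.04 close to background, or by 9.64 without the 2 arrays, and Gstp1, the pi-class glutathione S-transferase, by 6.76 (SE 1.01), or 7.70. Of 33 measured Nrf2 targets, 20 rose and 1 fell, or 21 and 2 adjusted over the list alone, with a median of 0.94 (adjusted p = 7.02e-14). The list gave adjusted p = 0.141 with an estimated correlation, and 0.0109 so without the 2 arrays. Microsomal epoxide hydrolase, Ephx1, rose by 2.24 (SE 0.24), and Nqo1 by 2.41 (SE 0.38). Of 18 glutathione S-transferases 12 rose and none fell, 14 adjusted over the list alone, with a median of 0.82 (adjusted p = 2.01e-13; adjusted p = 0.0680 with an estimated correlation). Gstt3 rose by 2.20 (SE 0.24) and Mgst2 by 2.14 (SE 0.28).

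Some genes that supply NADPH and build fatty acids rose as well under D3T; as labelled, neither list was called with an estimated correlation. Of 9 genes of the pentose phosphate pathway and NADPH supply 6 rose, 6 also adjusted over the list alone, with a median of 0.65 (adjusted p = 8.02e-06; adjusted p = 0.0680 with an estimated correlation). Malic enzyme, Me1, rose by 2.61 (SE 0.35) and 6-phosphogluconate dehydrogenase, Pgd, by 1.89 (SE 0.28). Me1 and Pgd are also in the list of Nrf2 targets. Of 22 genes of fatty acid synthesis 10 rose and 1 fell, or 12 and 1 adjusted over the list alone, with a median of 0.67 (adjusted p = 1.62e-07; adjusted p = 0.0680 with an estimated correlation). The desaturase Fads1 rose by 1.16 (SE 0.13) and the acetyl-CoA synthetase Acss2 by 1.33 (SE 0.19). Among 25 glutathione and thioredoxin redox enzymes 5 rose and 1 fell, or 7 and 1 adjusted over the list alone (median 0.29, adjusted p = 2.22e-04; adjusted p = 0.380 with an estimated correlation). Glutathione synthetase, Gss, rose by 0.95 (SE 0.14), while Gclc gave 0.30 (95% interval -0.09 to 0.68) and was not called; without the arrays labelled D3T 5 and OLT 1 it gave 0.39 (adjusted p = 0.0603), and it was called when the interquartile range was a covariate as well (adjusted p = 0.0337). Psat1, of serine synthesis, rose by 4.08 (SE 0.66) from a control mean of 2.52 at background, or by 4.72 without the arrays labelled D3T 5 and OLT 1, and Cryl1, an L-gulonate dehydrogenase, by 4.52 (SE 0.72), or 5.31.

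Of 16 measured heat shock genes 11 fell under D3T and none rose, 14 adjusted over the list alone, with a median of -0.72 (adjusted p = 3.29e-11; adjusted p = 0.0680 with an estimated correlation). The inducible Hsp70 gene Hspa1a fell from 10.33 ± 0.73 to 4.86 ± 1.24 (n = 5 each), by 5.46 (SE 0.56, adjusted p = 1.01e-05), and its co-chaperone Dnajb1 fell by 1.39 (SE 0.16). Of 28 genes of fatty acid oxidation and PPARa targets 14 fell and 2 rose, or 17 and 3 adjusted over the list alone, with a median of -0.36 (adjusted p = 3.38e-08; adjusted p = 0.201 with an estimated correlation). The pantetheinase Vnn1 fell by 4.22 (SE 0.35), the outer carnitine palmitoyltransferase Cpt1a by 2.65 (SE 0.28) and the dienoyl-CoA isomerase Ech1 by 2.30 (SE 0.21). Of 13 pericentral hepatocyte markers 5 fell and 1 rose, or 6 and 1 adjusted over the list alone, with a median of -0.65 (adjusted p = 0.0203; adjusted p = 0.380 with an estimated correlation, 0.0326 so without the 2 arrays). Glutamine synthetase, Glul, fell by 1.07 (SE 0.20) and Axin2, a target of Wnt signalling, by 1.66 (SE 0.30); the list was not called when limma used the D3T and control arrays alone (adjusted p = 0.0763). Of 16 genes of bile acid synthesis and transport 5 fell and 1 rose, or 7 and 1 adjusted over the list alone (median -0.44, adjusted p = 0.0135; adjusted p = 0.380 with an estimated correlation). Cyp8b1, the sterol 12-alpha-hydroxylase, fell by 1.80 (SE 0.22), while Cyp7a1, the rate-limiting enzyme of bile acid synthesis, gave -0.65 (95% interval -1.76 to 0.46). Noct, the clock-controlled nocturnin, fell by 5.37 (SE 0.64); the clock gene Per2, looked up after this was seen, fell by 4.39. The metallothionein gene Mt2A fell by 4.79 (SE 0.74), with -5.69 without the 2 arrays, and the cholesterol ester hydrolase gene Nceh1 fell by 4.57 (SE 0.57). The steroid hydroxylase gene Cyp17a1 fell by 4.83 (SE 0.42), to a mean of 2.91 at background. Cyp1a1 gave -0.06 (-2.17 to 2.05) and Cyp1a2 -0.19 (-0.57 to 0.19; -0.39 and called without the 2 arrays, adjusted p = 0.0248).

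In total 1502 probe sets were called between D3T and control, 599 higher and 903 lower, for 1023 genes; 527 also differed at least 2-fold, 183 higher and 344 lower. Without the arrays labelled D3T 5 and OLT 1 there were 1711 calls, and 1354 probe sets were called the same way in both fits. After quantile normalization 937 were higher and 941 lower, and without the array labelled D3T 3 the count was 969.

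OLT versus control addresses the response to the substituted dithiolethione. Some glutathione S-transferases and other Nrf2 targets rose, and some heat shock genes and genes of fatty acid oxidation fell; with an estimated correlation camera called 0 lists (5 at an unadjusted p under 0.05). Of 18 glutathione S-transferases 7 rose and none fell, 12 adjusted over the list alone, with a median of 0.55 (adjusted p = 4.19e-09; adjusted p = 0.252 with an estimated correlation). Gstt3 (gene ID 499422) rose from 11.42 ± 0.31 to 13.12 ± 0.49 (n = 5 each), by 1.70 (SE 0.24, adjusted p = 3.18e-04), and Gstm1 by 0.88 (SE 0.18). Of 33 Nrf2 targets 8 rose and 1 fell, or 13 and 2 adjusted over the list alone, with a median of 0.45 (adjusted p = 5.48e-08; adjusted p = 0.363 with an estimated correlation and 0.0798 by fry). Ephx1 rose by 1.70 (SE 0.24) and Akr7a3 by 2.57 (SE 0.61), or by 1.45 and 1.91 without the arrays labelled D3T 5 and OLT 1. Nqo1 gave 1.16 (95% interval 0.37 to 1.95) and was not called (adjusted p = 0.0723), with 0.79 and no call without the 2 arrays (adjusted p = 0.102). It was called after quantile normalization (adjusted p = 0.0320), with array weights (adjusted p = 0.0310), and without the 2 arrays with the interquartile range as a covariate (adjusted p = 0.0205). Of 9 genes of the pentose phosphate pathway and NADPH supply 3 rose, or 5 with 1 falling adjusted over the list alone (median 0.43, adjusted p = 0.00289; adjusted p = 0.252 with an estimated correlation). Those 3, Me1, Idh1 and Pgd, were all lost without the array labelled OLT 1 (adjusted p = 0.0987, 0.0539 and 0.114) or control 4 (0.0646, 0.0533 and 0.104). Me1 and Pgd were also lost without control 2, control 3, control 5 or OLT 2 (adjusted p from 0.0552 to 0.103), and Pgd without control 1 or OLT 4 (0.0569 and 0.0612); 1 of the 9 was called without both arrays labelled D3T 5 and OLT 1. Of 22 genes of fatty acid synthesis 4 rose, or 4 with 2 falling adjusted over the list alone (median 0.42, adjusted p = 3.75e-04; adjusted p = 0.292 with an estimated correlation and 0.0618 by fry). Srebf1, the transcription factor of lipid synthesis, rose by 1.09 (SE 0.19) and Fads1 by 0.82 (SE 0.13).

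Of 16 heat shock genes 6 fell under OLT and none rose, 6 also adjusted over the list alone, with a median of -0.28 (adjusted p = 6.16e-06; adjusted p = 0.252 with an estimated correlation). Hspa1a fell by 4.99 (SE 0.56) and Dnajb1 by 1.61 (SE 0.16). Of 28 genes of fatty acid oxidation and PPARa targets 11 fell and none rose, or 18 and 2 adjusted over the list alone, with a median of -0.41 (adjusted p = 5.28e-09; adjusted p = 0.252 with an estimated correlation). Vnn1 fell by 3.66 (SE 0.35), Ech1 by 1.55 (SE 0.21) and Cyp4a1, a fatty acid omega-hydroxylase, by 1.03 (SE 0.13). Cyp17a1 fell by 4.88 (SE 0.42), to a mean of 2.86 at background, Nceh1 fell by 3.95 (SE 0.57), and Aig1, a hydrolase of fatty acid esters, fell by 3.26 (SE 0.43). The ephrin ligand gene Efna1 rose by 2.67 (SE 0.36) and the ubiquitin ligase gene Rnf125 by 2.21 (SE 0.36). Cryl1 and Psat1 rose by 2.45 (SE 0.72, adjusted p = 0.0491) and 2.44 (SE 0.66, adjusted p = 0.0327). Without both arrays labelled D3T 5 and OLT 1 they were called at 1.73 (SE 0.23, adjusted p = 2.95e-04) and 2.04 (SE 0.50, adjusted p = 0.0255). With single arrays left out, Cryl1 was no longer called when any one control array or the array labelled OLT 1, OLT 3, OLT 4 or OLT 5 was left out (adjusted p from 0.0511 to 0.117). Psat1 was no longer called without the array labelled control 1, control 2, control 4, control 5, OLT 1 or OLT 5 (adjusted p from 0.0570 to 0.0921).

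Smaller list differences under OLT depended on single arrays. The 40 proteasome subunits had a median of 0.10, with 2 rising, 2 also adjusted over the list alone (adjusted p = 0.00869; adjusted p = 0.948 with an estimated correlation); the adjusted p was 0.0769 without the array labelled OLT 4 and 0.0554 without OLT 5. Those 2 genes, Psmb5 and Psmb10, were both lost without control 1, control 2, control 4 or OLT 1 (adjusted p from 0.0533 to 0.0900), and Psmb10 also without OLT 2, OLT 4 or OLT 5 (0.0507 to 0.0723). For 18 hepatocyte core genes the median was 0.18 with no gene called by limma over all genes or over the list alone (adjusted p = 0.00570; adjusted p = 0.474 with an estimated correlation, 0.870 after quantile normalization, and 0.0602 without the array labelled control 1). For 17 macrophage and Kupffer cell markers the median was -0.51 with 1 falling, 1 also adjusted over the list alone (adjusted p = 0.0171; adjusted p = 0.931 with an estimated correlation, 0.174 without the array labelled control 3 and 0.152 without OLT 4). That gene, Cd163, was lost without control 1, control 5, OLT 1, OLT 2 or OLT 3 (adjusted p from 0.0506 to 0.0708). Cyp1a1 gave 2.25 (95% interval 0.14 to 4.35, adjusted p = 0.193), and 3.13 without the 2 arrays, where it was called (adjusted p = 0.0201). Cyp1a2 gave 0.41 (0.03 to 0.79), and 0.52 without them, also called there (adjusted p = 0.0107). Gclc gave -0.03 (-0.41 to 0.35) and Cyp7a1 0.87 (-0.24 to 1.99).

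In total 826 probe sets were called between OLT and control, 198 higher and 628 lower, for 588 genes; 311 also differed at least 2-fold, 61 higher and 250 lower. Without the arrays labelled D3T 5 and OLT 1 there were 594 calls, 530 of them shared with the fit of all arrays. After quantile normalization 505 were higher and 652 lower, and of those at least 2-fold 96 were higher and 216 lower; centring the arrays moved the median of all kept probe sets to -0.10. Leaving out a single array gave 523 calls (control 1), 524 (control 2), 544 (control 5), 532 (OLT 1) or 1310 (OLT 5, with 470 at least 2-fold).

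**Figure D2:**
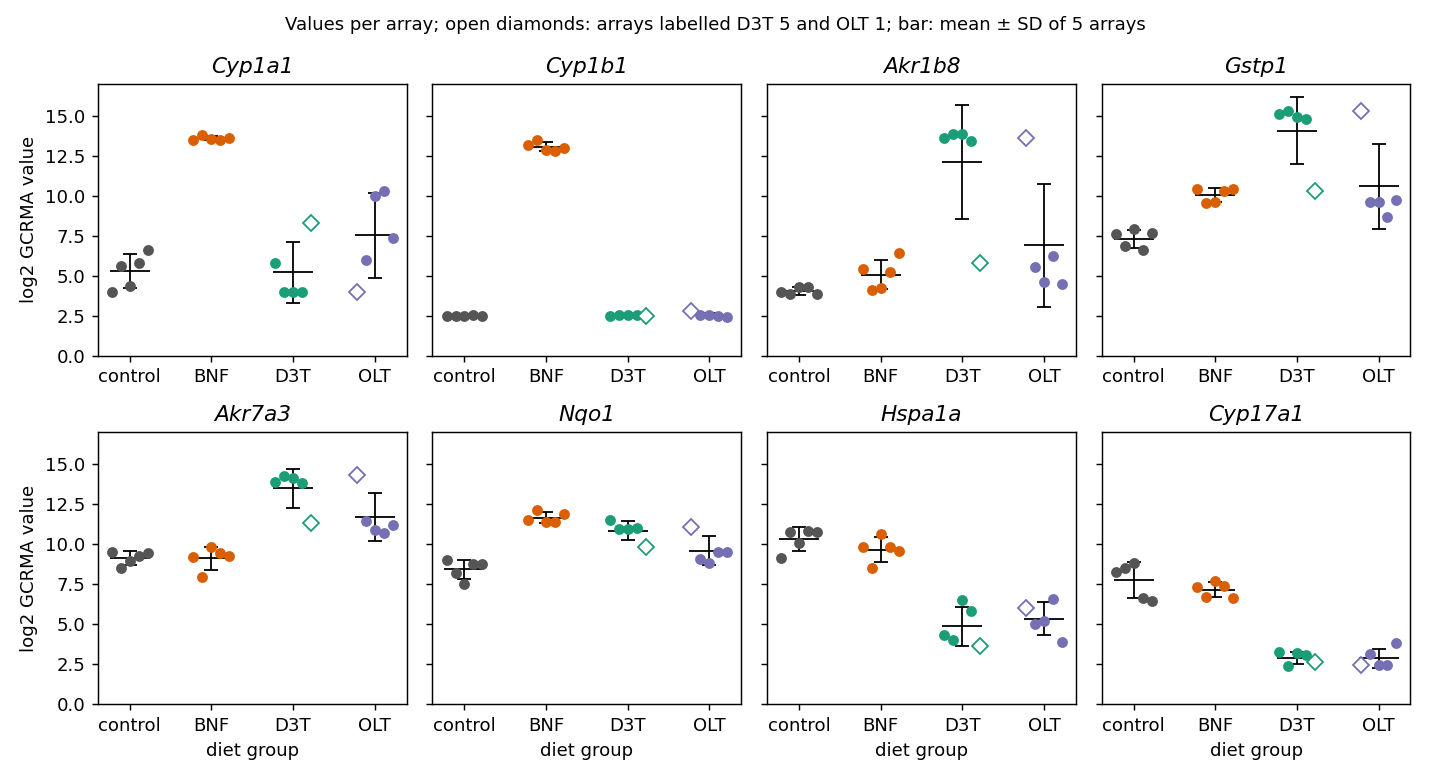
Log2 GCRMA value (vertical axis) per array for 8 genes by diet group (horizontal axis); points are arrays, bars show mean ± SD of 5 arrays, and open diamonds mark the arrays labelled D3T 5 and OLT 1. Cyp1a1 reaches a mean of 13.59 under BNF, Akr1b8 reads 5.77 in the array labelled D3T 5 and 13.61 in the array labelled OLT 1, and Hspa1a is low under both dithiolethiones.

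OLT versus D3T sets the compound with a methyl and a pyrazinyl group on the ring beside the parent ring, at doses that differed (500 and 600 mg per kg of diet), so that a difference cannot be assigned to structure or dose. As labelled, limma called 0 probe sets, with 1385 at an unadjusted p under 0.05. With array weights, an alternative fixed beforehand, it called some, with counts given in the section on the processing. Without the arrays labelled D3T 5 and OLT 1 it called 549, of which 229 were higher and 320 lower under OLT, for 378 genes; 227 differed at least 2-fold, 101 higher and 126 lower. Leaving out the array labelled D3T 5 alone gave 236 calls (109 at least 2-fold), OLT 1 alone gave 131 (64 at least 2-fold), and D3T 4 alone gave 1. The intervals of the difference were wide as labelled: Akr7a3 gave -1.79 (95% interval -3.07 to -0.51, adjusted p = 0.286), Gstp1 -3.50 (-5.61 to -1.38) and Nqo1 -1.25 (-2.04 to -0.47). Without the 2 arrays they narrowed, to -2.99 (-3.65 to -2.32) for Akr7a3, -5.61 (-6.24 to -4.99) for Gstp1, and -1.88 (-2.47 to -1.30) for Nqo1, all called as lower under OLT than under D3T. Since the 2 arrays were left out for lying toward the other group, wider differences and narrower intervals follow in part from that choice. In that fit Me1, with -1.95 (-2.47 to -1.43), and Ephx1, with -0.94 (-1.30 to -0.59), were also called lower. Called higher under OLT were Mt2A by 4.26 (3.56 to 4.95), Noct by 3.46 (2.03 to 4.89), Cyp1a1 by 3.97 (2.34 to 5.59) and Cyp1a2 by 0.92 (0.67 to 1.16).

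For several genes lowered by both compounds no difference was called between them in either fit. As labelled, Hspa1a differed by 0.47 (95% interval -0.71 to 1.65), Vnn1 by 0.55 (-0.18 to 1.29), Dnajb1 by -0.22 (-0.55 to 0.11) and Nceh1 by 0.62 (-0.57 to 1.81), OLT minus D3T. These intervals leave room for differences of the size of 1 log2 unit for Hspa1a, Vnn1 and Nceh1. Srebf1, which was higher than control under both compounds, differed by -0.02 (-0.42 to 0.37).

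By camera at the preset correlation 9 lists differed between OLT and D3T as labelled, though limma called no member over all genes, and none of the 9 was called with an estimated correlation. The Nrf2 targets were lower under OLT, with a median of -0.53 and 17 of 33 lower adjusted over the list alone (adjusted p = 6.24e-08; adjusted p = 0.431 with an estimated correlation and 0.0870 by fry). Without the 2 arrays 22 of the 33 were called lower and 1 higher over all genes (adjusted p = 0.0130 with an estimated correlation). Glutathione S-transferases had a median of -0.27, with 4 of 18 lower adjusted over the list alone (adjusted p = 4.55e-05; adjusted p = 0.431 with an estimated correlation), and 9 called lower without the 2 arrays. The pentose phosphate and NADPH list had a median of -0.49, with 5 of 9 lower adjusted over the list alone (adjusted p = 7.60e-04; adjusted p = 0.339 with an estimated correlation). Fatty acid synthesis had a median of -0.40, with 9 of 22 lower adjusted over the list alone (adjusted p = 2.59e-04; adjusted p = 0.374 with an estimated correlation). Glutathione and thioredoxin redox enzymes had a median of -0.26, with 1 of 25 lower adjusted over the list alone (adjusted p = 2.14e-04; adjusted p = 0.431 with an estimated correlation). Genes of ER stress and the unfolded protein response had a median of -0.23, with 6 of 24 lower adjusted over the list alone (adjusted p = 5.12e-05; adjusted p = 0.519 with an estimated correlation), and 9 called lower without the 2 arrays. Pericentral hepatocyte markers were higher under OLT, with a median of 0.40 and 4 of 13 higher adjusted over the list alone (adjusted p = 5.12e-05; adjusted p = 0.339 with an estimated correlation), and 5 called higher without the 2 arrays (adjusted p = 0.0115 with an estimated correlation). Heat shock genes had a median of 0.21, with 4 of 16 higher adjusted over the list alone (adjusted p = 5.12e-05; adjusted p = 0.374 with an estimated correlation). Proteasome subunits had a median of 0.12, with 0 of 40 called by limma adjusted over the list alone (adjusted p = 5.12e-05; adjusted p = 0.541 with an estimated correlation). By fry none of the 9 lists was called.

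**Figure D3:**
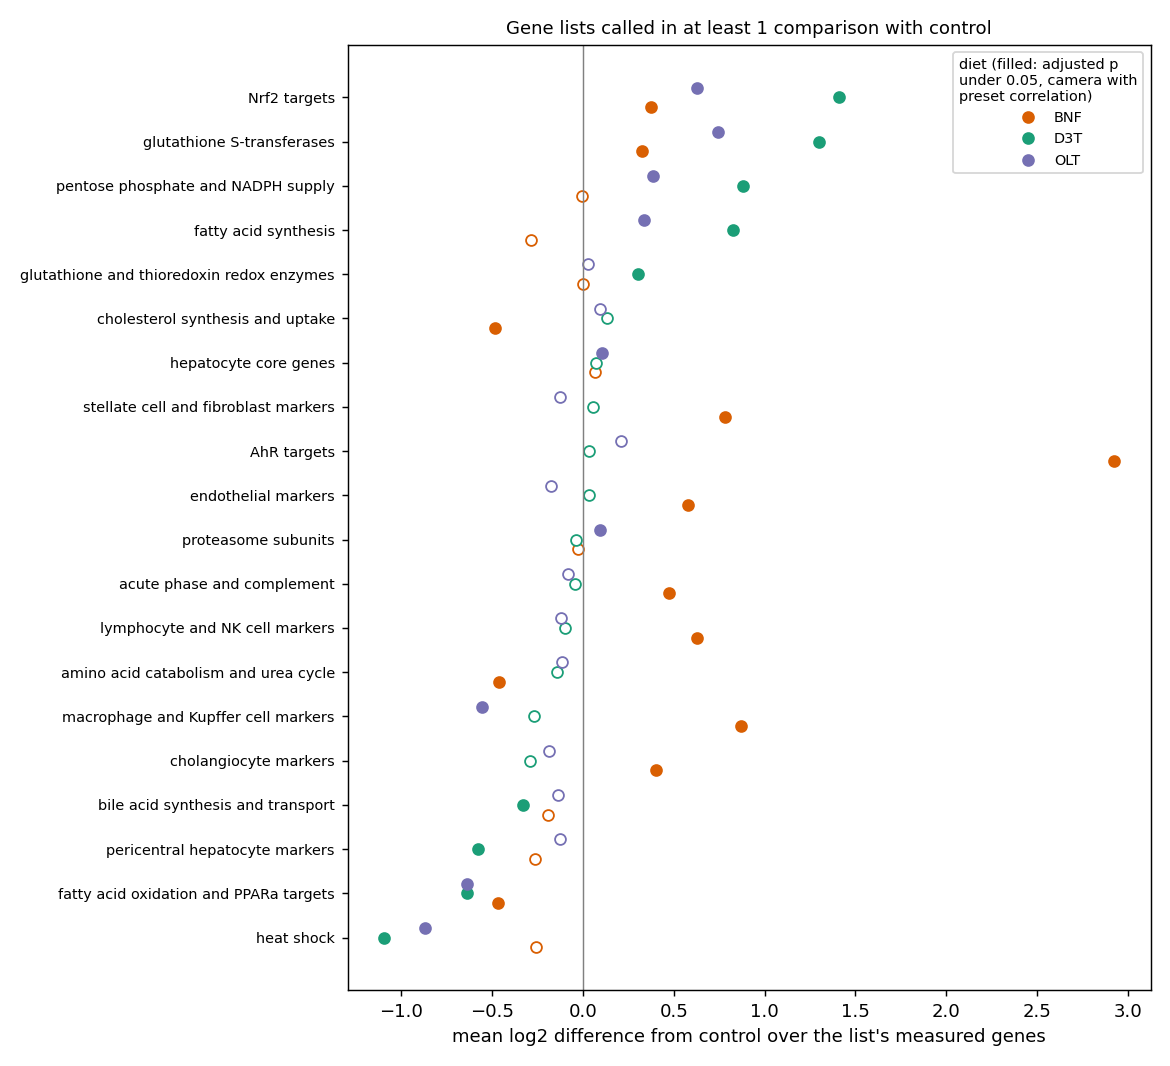
Mean log2 difference from control (horizontal axis) over the measured genes of each list (vertical axis) for BNF, D3T and OLT; filled points have an adjusted p under 0.05 by camera with the preset correlation; with an estimated one the AhR targets under BNF were the only list called, among these 3 comparisons. The AhR targets lie farthest to the right under BNF, with a mean of 2.92, and the Nrf2 targets have means of 1.41 under D3T and 0.63 under OLT.

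BNF versus D3T and BNF versus OLT set the AhR ligand beside the dithiolethiones. The P450 genes Cyp1a1 and Cyp1b1 were higher under BNF, by 8.39 (SE 1.01) and 10.54 (SE 0.11) against D3T, and by 6.08 (SE 1.01) and 10.51 (SE 0.11) against OLT. For Cyp1a1 the differences were 9.16 (SE 0.73) and 5.19 (SE 0.73) without the arrays labelled D3T 5 and OLT 1. Rbm24 was higher by 7.39 (SE 0.14) and 7.36 (SE 0.14); D3T and OLT means of Cyp1b1 and Rbm24 lay at background. Lower under BNF were Dao, by -4.68 (SE 0.57) against D3T and -3.46 (SE 0.57) against OLT, and Spink1l, by -5.23 (SE 0.62) and -3.86 (SE 0.62). Cryl1 was lower by -5.20 (SE 0.72) against D3T, or -5.98 (SE 0.23) without the 2 arrays, and Aspg by -4.36 (SE 0.34) against OLT. Of 11 AhR targets 7 were higher and 1 lower than under D3T, or 10 and 1 adjusted over the list alone (adjusted p = 1.56e-09; adjusted p = 0.00223 with an estimated correlation), and 9 were higher and 1 lower than under OLT, 9 and 1 also adjusted over the list alone (adjusted p = 3.09e-10; adjusted p = 0.00179 with an estimated correlation). Of 17 macrophage and Kupffer cell markers 12 were higher than under D3T and 16 higher than under OLT, with medians of 1.15 and 1.48; adjusted over the list alone the counts were 16 and 16 (adjusted p = 2.16e-08 and 6.18e-12; adjusted p = 0.203 and 0.187 with an estimated correlation). Glutathione S-transferases were lower under BNF for 13 of 18 against D3T and 6 of 18 against OLT; adjusted over the list alone, 15 and 8 were lower and 1 was higher in each (adjusted p = 9.87e-08 and 5.96e-04; adjusted p = 0.203 and 0.412 with an estimated correlation). Fatty acid synthesis genes were lower for 13 of 22 against D3T, with 1 higher, and for 10 of 22 against OLT; adjusted over the list alone, 14 and 12 were lower and 1 was higher in each (adjusted p = 2.17e-07 and 5.77e-05; adjusted p = 0.126 and 0.187 with an estimated correlation). Camera called 15 lists between BNF and D3T and 14 between BNF and OLT, of which the AhR targets alone held with an estimated correlation.

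In total 1935 probe sets were called between BNF and D3T, 808 higher and 1127 lower under BNF, for 1376 genes, with 684 at least 2-fold (388 higher, 296 lower). Between BNF and OLT 1246 were called, 690 higher and 556 lower, for 916 genes, with 493 at least 2-fold (344 higher, 149 lower). Without the arrays labelled D3T 5 and OLT 1 the counts were 1973 and 1022. With the arrays centred on their median, 607 were higher and 315 lower against OLT, and without the array labelled BNF 1 the count against OLT was 777.

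The changes under D3T and OLT resembled each other across genes more than either resembled those under BNF. Across the 12947 probe sets the log2 changes against control correlated with r = 0.776 between D3T and OLT, 0.227 between BNF and D3T and 0.266 between BNF and OLT; probe sets are not independent replicates. All 3 changes share the 5 control arrays, and simulated unchanged groups that share controls gave r = 0.50 for each pair. The standard errors of r, from leaving out each array in turn, were 0.108, 0.0960 and 0.128 in the same order of pairs. The covariance of the real changes exceeded the simulated one by 0.142 for D3T and OLT, by 0.0180 for BNF and D3T and by 0.0173 for BNF and OLT. The simulated noise was drawn independently for each probe set, which the real residuals were not. The small excesses of the pairs with BNF therefore need not reflect shared responses. With the controls split so that the changes shared none, r was 0.616, 0.111 and 0.128. Leaving out the arrays labelled D3T 5 and OLT 1 gave 0.625, 0.22 and 0.292. D3T and OLT both raised 142 probe sets, both lowered 397, and moved 0 called by limma in opposite directions; without the arrays labelled D3T 5 and OLT 1 these counts were 99, 271 and 4. BNF and D3T both raised 21 and both lowered 75, with 29 opposite (37, 97 and 45 without the 2 arrays). BNF and OLT both raised 15 and both lowered 62, with 6 opposite (27, 57 and 5). In 20 simulations of unchanged groups with shared controls and the same independent noise, limma called 0 probe sets in both the D3T and the OLT change. What shared controls add beside real changes was not computed. The p53 target Gadd45a was among the genes that moved apart: it rose by 1.01 (SE 0.23) under BNF and fell by 1.26 (SE 0.23) under D3T and by 1.37 (SE 0.23) under OLT, although the call under BNF was lost without the array labelled control 1 (adjusted p = 0.0537).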

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

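In this part the test of cell shares was written before its result was seen; the other tests, on the exchanged labels, the clock genes, the spread of intensities and the splits of the arrays, were chosen after the results they concern had been seen.

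Values of single arrays that stood far from the 4 others of their group were found for 37 of 464 pairs of a gene and a group (116 named genes), where chance alone gives about 1 in 20, or 23.2; 18 of the 37 lay within 1 log2 unit of the nearest other array. The array labelled OLT 1 held 12 of them. There the aldo-keto reductases Akr1b8 and Akr7a3 read 13.61 and 14.33, the transferases Gsta3, Gstp1, Gstt3 and Mgst2 read 12.02, 15.26, 13.96 and 11.88, and Cryl1 read 10.69. Gclc read 10.85, Pgd 11.15, Ugdh 13.10, Acss2 11.91 and Mlxipl 8.29, all 12 above the other OLT arrays.

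The array labelled D3T 5 held 11. Below the other D3T arrays were Akr1b8 at 5.77, Akr7a3 at 11.35, Cryl1 at 6.73, Gsta3 at 10.90, Gstp1 at 10.30, Me1 at 9.84, Mgst2 at 10.68 and Txn1 at 13.39. Above them were Cyp1a2 at 14.51, Lcn2 at 4.22 and Mt2A at 11.68.

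A candidate explanation for these 2 arrays is that their labels were exchanged: between the other OLT arrays at 0 and the other D3T arrays at 1 the array labelled D3T 5 stood at 0.158 and the array labelled OLT 1 at 0.807, where other D3T arrays stood at 0.854 to 0.987 and other OLT arrays at 0.0378 to 0.221. A weaker response of the rat labelled D3T 5 to D3T, the biological explanation tested, is argued against by 60 probe sets that moved under OLT and not in the other D3T arrays. The array labelled D3T 5 showed a median share of 0.890 of that OLT change, where other D3T arrays, each on 43 to 59 probe sets chosen without it, showed 0.0892 to 0.228 and other OLT arrays 0.503 to 0.883; the array labelled OLT 1 showed 0.356, in between. Mixing of the 2 RNA samples in equal parts is argued against by the position of 0.807. Whether labels were exchanged among rats, samples or arrays stays open, and the labels were kept as deposited.

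Some genes of the circadian clock, looked up after the values of Noct had been seen, were low in the dithiolethione arrays: Per2 fell by 4.39 under D3T (adjusted p = 2.81e-05) and by 2.21 under OLT, Per1 fell by 1.61 and by 1.13, and Usp2 fell by 3.29 and Hlf fell by 1.26 under D3T, so that 4 of 9 late-day genes were called lower under D3T, 2 under OLT and 0 by limma under BNF. A shift of all values by the normalization is argued against, since the median of all kept probe sets moved by -0.0243 under D3T. Collection of tissue at another time of day and an effect of the compounds on the clock, which was not tested, cannot be told apart. Within groups the late-day and opposite-phase genes correlated over the 20 arrays with r = -0.406 (permutation p = 0.0761; rho = -0.420, p = 0.0661; r = -0.345 without the 2 farthest arrays). Of 4 opposite-phase genes 2 lay above control under D3T, of which Npas2 was called (1.47, adjusted p = 0.0207) and Clock was not, Nfil3 was called lower under OLT (-1.16, adjusted p = 0.0247), and the median under D3T was -0.16; the bound to which this median was held was reworded after it had been seen; against a bound of 0 it would argue against the time of day.

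Other splits of the 10 arrays of a comparison were fitted to the 2 groups alone, 100 drawn of 126 possible with the real one among them. The real split called more than every other drawn one for BNF versus control (481 probe sets called, highest other split 15), D3T versus control (1252, highest other 28), OLT versus control (382, highest other 178), BNF versus D3T (1762, highest other 40) and BNF versus OLT (902, highest other 42). In each, 1 split of 100, the real one, called as many. With the real split among the 100, this share cannot be lower, so chance was made unlikely and not excluded. For OLT versus D3T the splits say nothing about chance: limma called 0 in the real split (1385 at an unadjusted p under 0.05), so all 100 splits call as many by construction. The highest other split called 1194.

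A split of the D3T and OLT arrays that calls 1194 probe sets points to a structure of the samples; it exchanged the arrays labelled D3T 2 and D3T 3 with OLT 4 and OLT 5. Exchanged labels of D3T 5 and OLT 1 do not account for this split, since 0 of these 2 arrays were among those exchanged in it. Whether the labels were exchanged is a separate question that this split cannot decide. The split exchanging only these 2 arrays called 353, the second highest. The structure may follow the spread of intensities: interquartile ranges were 3.69 to 3.91 on one side and 4.00 to 4.27 on the other, the calls dropped to 399 after quantile normalization, and within groups the first component of the residuals followed the interquartile range (20 arrays, r = 0.964, rho = 0.958, permutation p = 1e-05 for both, the smallest possible; r = 0.941 without the 2 farthest arrays). Different shares of cells other than hepatocytes in the tissue pieces stay open: medians on the side of low spread were -0.88 for 12 endothelial, -0.43 for 17 macrophage, -0.29 for 14 stellate cell, -0.16 for 7 lymphocyte and -0.07 for 7 cholangiocyte markers, 0 of them in another list. No other biological explanation was tested.

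The remaining values far from their group were as follows. Under BNF, the array labelled BNF 2 read 10.31 for Dnajb1, 14.88 for Orm1 and 6.68 for Vnn1, BNF 5 read 5.37 for Hspb1 and 13.46 for Idh1, and BNF 1 read 11.92 for Col3a1. Under D3T, the array labelled D3T 1 read 13.88 for Cdo1 and D3T 2 read 3.97 for Tyrobp. Under OLT, the array labelled OLT 5 read 3.39 for Lcn2 and 9.50 for Nr1i2, OLT 2 read 6.76 for Spink1l, OLT 3 read 7.79 for Psmb10 and OLT 4 read 3.30 for Dcn. The array labelled control 3 read 13.82 for Cat.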

How the results depend on the processing

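Of the alternatives here, those that leave out the arrays labelled D3T 5 and OLT 1 and those with the interquartile range as a covariate are tests chosen after the results had been seen; the others were fixed beforehand. No called gene or list and no correlation reversed under any alternative run. Differences near 0 that were not called did change sign between OLT and D3T without the arrays labelled D3T 5 and OLT 1, such as Hspa1a (0.47 and -0.00496) and Srebf1 (-0.02 and 0.0121). Where no cause is given for a change below, the cause was not tested.

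Array weights raised the counts called to 1480 (BNF versus control), 2885 (D3T), 2054 (OLT), 112 (OLT versus D3T), 3337 (BNF versus D3T) and 2767 (BNF versus OLT), with 286 for BNF and 51 for OLT versus D3T at least 2-fold. Centring the arrays gave 299 for BNF. Without a filter 974 were called for D3T and 457 for OLT, and 20 lists for BNF. With only the 2 groups compared, 382 were called for OLT and 481 for BNF. The interquartile range as a covariate gave 744 for BNF, or 877 with the arrays labelled D3T 5 and OLT 1 left out as well. For OLT versus D3T, where limma called 0 as labelled (1385 at an unadjusted p under 0.05), leaving out these 2 arrays gave 549, with 227 at least 2-fold, and adding the covariate gave 1174 and 296. Leave-one-out is given below; the other alternatives kept every total count of probe sets within 1.5 times that in the report. Counts in one direction moved further with the scaling. Quantile normalization gave 311 higher for BNF (189 in the report), 937 for D3T (599) and 505 for OLT (198; at least 2-fold 96 and 61), so that the balance under BNF turned from lower to higher, and 863 lower for BNF versus OLT (556). Centring gave 124 higher for BNF and 99 for OLT, and 315 lower for BNF versus OLT.

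Camera with the correlation estimated per list called 1 list for BNF, 0 for D3T (6 at an unadjusted p under 0.05), 0 for OLT (5), 0 for OLT versus D3T (4), 1 for BNF versus D3T and 1 for BNF versus OLT. Without the arrays labelled D3T 5 and OLT 1 it called 1, 4, 0 (4 unadjusted), 6, 2 and 1 in the same order. Fry called 4 for OLT and 0 for OLT versus D3T (7 unadjusted).

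With the controls split so that no control array was shared, changes correlated with r = 0.111 (BNF and D3T), 0.128 (BNF and OLT) and 0.616 (D3T and OLT). With all controls shared, D3T and OLT correlated with r = 0.776, and 0.625 without the arrays labelled D3T 5 and OLT 1.

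Leaving out each array in turn gave 263 to 478 calls for BNF, 969 to 1538 for D3T, 523 to 1310 for OLT, 0 to 236 for OLT versus D3T by limma, 1344 to 2180 for BNF versus D3T and 777 to 1675 for BNF versus OLT. At least 2-fold there were 120 to 202, 404 to 589, 227 to 470, 0 to 109, 567 to 847 and 380 to 684. Counts moved by over 1.5 times without the array labelled control 2 (297), BNF 1 (263) or BNF 2 (291) for BNF, D3T 3 (969) for D3T, and control 1 (523), control 2 (524), control 5 (544), OLT 1 (532) or OLT 5 (1310; 470 at least 2-fold) for OLT. They also did so without D3T 4 (1), D3T 5 (236; 109) or OLT 1 (131; 64) for OLT versus D3T, and BNF 1 (777) for BNF versus OLT. Lists called ranged over 12 to 17, 9 to 10, 7 to 10, 9 to 11, 14 to 16 and 11 to 15, and r over 0.178 to 0.299, 0.212 to 0.360 and 0.702 to 0.806.

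Of 171 named gene results, 159 of them called, calls were lost for 29 with only the 2 groups compared, 27 without a filter, 19 after centring, 13 without the 2 arrays (3 gained), 11 with the covariate (8 lost and 5 gained without the 2 arrays as well), 5 after quantile normalization (1 gained), 4 with the mean of probe sets, and 1 each with array weights (1 gained), no trend and a robust prior. Leave-one-out lost 177 calls, counted over genes and arrays left out, and left 1533 results, called or not, on the same side of the threshold. With the stricter filter none of the 165 results measured changed its side. Of 39 list results, 38 were lost with an estimated correlation (28 without the 2 arrays), 17 by fry, 2 each with the stricter filter and the covariate, 1 each with the covariate and the 2 arrays left out, no filter, only the 2 groups and quantile normalization, and 5 on leave-one-out, where 385 were kept.

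With the replicate number as a replicate block, 419 probe sets were called for BNF, 1578 for D3T, 870 for OLT and 0 by limma for OLT versus D3T; 8 named genes lost their call and 1 gained one (Nqo1 under OLT, adjusted p = 0.0480). Residuals of arrays with one number correlated between -0.272 and 0.297, and for 2 arrays the closest array of another group had the same number. Means near the background level limit changes that start or end there, and no alternative removes this.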

Other observations

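In this part the test of neighbouring genes was written before its result was seen, and the rule for genes split within groups and the tests without the arrays labelled D3T 5 and OLT 1 were chosen after values had been seen.

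Several lists were not called by camera with the preset correlation yet held genes called over all genes. Under OLT, genes of the unfolded protein response were lower for 4 of 24 measured: the ER co-chaperone gene Dnajb9 fell by 1.92 (SE 0.36) and Herpud1, of ER-associated degradation, fell by 2.00 (SE 0.40). Without the arrays labelled D3T 5 and OLT 1 camera called this list, lower under OLT (adjusted p = 0.00318; adjusted p = 0.740 as labelled) and higher under D3T (adjusted p = 0.00316; adjusted p = 0.115 as labelled), and with an estimated correlation it called neither (adjusted p = 0.572 and 0.510). Of 21 CAR and PXR targets 5 fell and 3 rose under D3T, and 2 fell under OLT. The P450 reductase gene Por fell by 1.88 (SE 0.22) under D3T and by 1.14 (SE 0.22) under OLT, and the receptor gene Nr1i2 fell by 0.90 (SE 0.14) and by 0.73 (SE 0.14), the last not called when limma used the OLT and control arrays alone (adjusted p = 0.0534). The sulfotransferase gene Sult1c3 fell by 4.09 (SE 0.70) under D3T. Under OLT it gave -2.79 (SE 0.70), called as labelled and not without the array labelled control 5 (adjusted p = 0.0589) or OLT 1 (adjusted p = 0.0604); without both D3T 5 and OLT 1 it was called at -2.21 (adjusted p = 0.0185).

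Of 31 genes of amino acid catabolism and the urea cycle, 6 fell and 4 rose under D3T: argininosuccinate lyase, Asl, fell by 1.06 (SE 0.13) and tyrosine aminotransferase, Tat, fell by 1.06 (SE 0.16). Glycogen synthase of liver, Gys2, fell by 1.45 (SE 0.27) under D3T and by 1.20 (SE 0.27) under OLT. Of 20 genes of cholesterol synthesis and uptake 3 rose under D3T, among them Dhcr7 by 1.40 (SE 0.25). Of 20 genes of iron and heme 2 rose and 1 fell under D3T, where ferrochelatase, Fech, rose by 0.93 (SE 0.19). Under OLT 1 rose and 3 fell, and ferroportin, Slc40a1, fell by 0.72 (SE 0.10). Under BNF 3 fell and none rose, and hemojuvelin, Hjv, fell by 0.90 (SE 0.19). Also under BNF the bile acid receptor gene Nr1h4 fell by 0.82 (SE 0.17), the carboxylesterase gene Ces2c fell by 0.95 (SE 0.19) and the acetyl-CoA carboxylase gene Acaca fell by 1.13 (SE 0.24), while Glrx, glutaredoxin, rose by 0.85 (SE 0.13) and Apoa1 by 0.78 (SE 0.17).

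Some genes were split within groups, with a gap of at least 2 log2 units that parted arrays of at least 2 groups and left at least 3 arrays on each side; 11 genes met this rule. The class II histocompatibility gene RT1-Ba read 3.26 to 4.02 in the arrays labelled control 5, D3T 1, D3T 2, D3T 4 and D3T 5 and at least 6.91 in the others. RT1-Bb read at most 3.36 in control 5, D3T 1, D3T 2 and D3T 5 and at least 6.20 in the others. Pxmp4 read at most 6.497 in control 1, control 2, BNF 4 and OLT 5 and at least 9.22 in the others. Ubd read at most 6.15 in 9 arrays and at least 8.18 in the others. The other 7 were Akr1b8, Gstp1, Cryl1, Akr7a3, Psat1, Mt2A and Isyna1. In each of these the array labelled D3T 5 lay with most other OLT arrays and the array labelled OLT 1 with the other D3T arrays. These 7 thus repeat the pattern of those 2 arrays.

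Genes raised at least 2-fold by BNF were tested for lying next to each other on chromosomes more often than chance, with a negative result. Among 72 such genes there was 1 adjacent pair, Mybl1 and Vxn, where random draws of as many measured genes gave a mean of 0.287 and 2516 of 10000 draws gave as many (one-sided permutation p = 0.252).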
